A study of Thermothelomyces thermophilus with 14 samples.

How the data were processed

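RNA sequencing was done on 14 libraries of wild-type Myceliophthora thermophila mycelium, 7 groups of 2, all taken 4 h after transfer. Groups and replicate numbers came from the sample titles. The flask group called XA in the sample titles is called AX in the growth protocol and in the count table, and the 2 were taken as the same group because both name Avicel with xylan. The values were counts of reads per gene, as the authors deposited them, with no normalization. TopHat2 2.0.8b and HTSeq 0.13.5 are named per the submitters' processing notes; the genome build, annotation and strand setting are not given in the sources used here. Without a stated strand setting, reads from overlapping neighbours or antisense genes cannot be told apart, and close paralogs may share reads.

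The table held 9110 gene identifiers, of which 9087 matched a locus tag of the NCBI reference table for assembly ASM22609v1. That table carries no product names, and its symbols repeat the locus tags. The 25 gene lists that had been defined by product-name patterns therefore found 0 members and could not be tested. The trivial names used here for 28 loci (such as cbh-1, cdt-2 and gh1-1) come from published locus assignments as remembered, not from the reference table, which neither gives nor contradicts them. Of these loci, 19 were fixed before the data were examined, and 9 (LPMO9E, LPMO9H, LPMO9J, eg-45 and lat-1 with the 4 xylanases) were added after the table had been opened and before any test. The assignment of cdt-1 (MYCTH_43941) is the least sure, and its level was below 8 CPM in each group. No coordinates are given, because the build behind the counts is not stated.

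Counts were analysed with edgeR 4.0.16 in R 4.3.3. Genes were filtered with filterByExpr at its default minimum count of 10, which left 8567 genes and removed 543, of which 153 had no count in any library. Library sizes were scaled by TMM. A single quasi-likelihood model with 7 group means was fitted to all 14 libraries (7 residual degrees of freedom, robust), so that groups of 2 shared an estimate of the spread. A gene was called when its Benjamini-Hochberg adjusted p was under 0.05 over all genes tested in that comparison. In all, 10 comparisons were planned, the last being the departure from additivity, (G2X2 minus G2) minus (X2 minus NoCarbon2) on the log2 scale. Tests are two-sided unless stated. CPM values use the TMM-scaled library sizes. Standard errors were taken from the log2 fold change and its F statistic, and 95% intervals from the matching t distribution. Where both libraries of a group had no count, a bound is given against 3 counts over the group, which covers counting error only.

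The design, the comparisons, the alternatives and the rule for naming genes were set before the data were examined. The rule names the 19 loci fixed beforehand, and the 9 loci added later were named as well. For each comparison it also names called genes with no informative product, the 2 with the largest rise and the 2 with the largest fall. Such genes need a mean of at least 20 CPM in the higher group. They also need no overlap between the libraries of the groups, except for the departure from additivity. A further part of the rule, for genes with informative product names, named none.

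Lists were tested with camera (limma 3.58.1) at a preset inter-gene correlation of 0.01, over 6 lists of at least 3 members and 10 comparisons, 60 tests adjusted together. Of these, 32 were called, and 0 with a correlation estimated from the data, where 13 had an unadjusted p under 0.05; fry called 29. Among the 19 loci fixed before the data were examined, 13 rose and 1 fell in XA versus Xylan over all genes, and 13 and 2 when adjusted over the list alone. For G2 versus NoCarbon2 the numbers were 13 and 0, and 13 and 1 adjusted over the list alone. For X2 versus NoCarbon2 they were 7 and 1, and 8 and 1 adjusted over the list alone, and for X2 versus G2 3 and 9, and 4 and 10 adjusted over the list alone. In the other comparisons both ways of adjusting gave equal numbers: 13 and 3 for G2X2 and 4 and 3 for GX versus NoCarbon2, 2 and 0, 10 and 3, and 12 and 1 for G2X2 versus G2, X2 and GX, and 1 and 7 for the departure from additivity. The 19 loci as a list were called higher in XA versus Xylan (camera adjusted p = 1.88e-08; adjusted p = 0.223 with an estimated correlation). The cellulase and LPMO list holds 4 added loci; with only its 9 earlier loci, 8 rose with cellobiose (camera adjusted p = 7.09e-09; adjusted p = 0.194 with an estimated correlation). The lists of disaccharide genes and of regulators were called higher in XA versus Xylan (camera adjusted p = 0.00273 and 0.016; adjusted p = 0.292 and 0.332 with an estimated correlation).

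The model was tested on simulated data for G2 versus NoCarbon2, with counts drawn from the fitted means, library sizes and dispersions over 8525 genes. Both groups were given the fitted NoCarbon2 means, and only the genes counted next were changed in G2. Of 100 genes changed 2-fold 27 were recovered, and of 100 changed 4-fold 86, with 11 false calls among 124. Changes of 2-fold were thus often missed where few genes changed. The data themselves gave 2274 calls in this comparison, which loosens the cutoff for a call, so these shares do not carry over to them. The absence of a call still does not show that a gene was alike in 2 groups. Alternatives were DESeq2 1.42.0 (its size factors within edgeR, and its Wald test), upper-quartile factors, no filter, fewer groups in the fit, a replicate block, stricter thresholds and leaving out each library. Groups of 2 do not allow other splits of the samples to be counted or single outlying libraries to be tested. Figures were drawn with matplotlib from the same values.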

Results

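The data describe messenger RNA in wild-type mycelium of the thermophilic filamentous fungus Myceliophthora thermophila 4 h after pregrown mycelium was moved to a defined carbon source. There were 14 libraries in 7 groups of 2. A flask experiment used 100 mL cultures with 2% xylan (Xylan) or with 1% Avicel, a microcrystalline cellulose, and 1% xylan (XA). A plate experiment used 5 mL cultures in 24-well plates with no carbon source (NoCarbon2), 2% cellobiose (G2), 2% xylobiose (X2), both disaccharides at 2% each (G2X2), or 1% glucose with 1% xylose (GX). Cellobiose is a disaccharide of glucose released from cellulose, and xylobiose is a disaccharide of xylose released from xylan. Each library held between 17992946 and 25254924 counts assigned to genes. Replicate libraries correlated across genes at r between 0.965 (NoCarbon2) and 0.992 (XA), while libraries of different groups correlated at 0.86 to 0.961. Replicate counts differed by more than sampling noise in each group (chi-square per gene 21.0 to 227.6), so no pair looked like a library entered a second time. Levels are CPM, counts scaled to a common library size, as mean ± SD with n = 2, and changes are log2 fold changes ± SE with adjusted p from edgeR. Genes without a name are those with the largest called changes of each comparison under the rule given with the methods. The labels do not say that replicates came from separate cultures, so p-values measure only the spread between these samples, which may be technical.

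**Figure D1:**
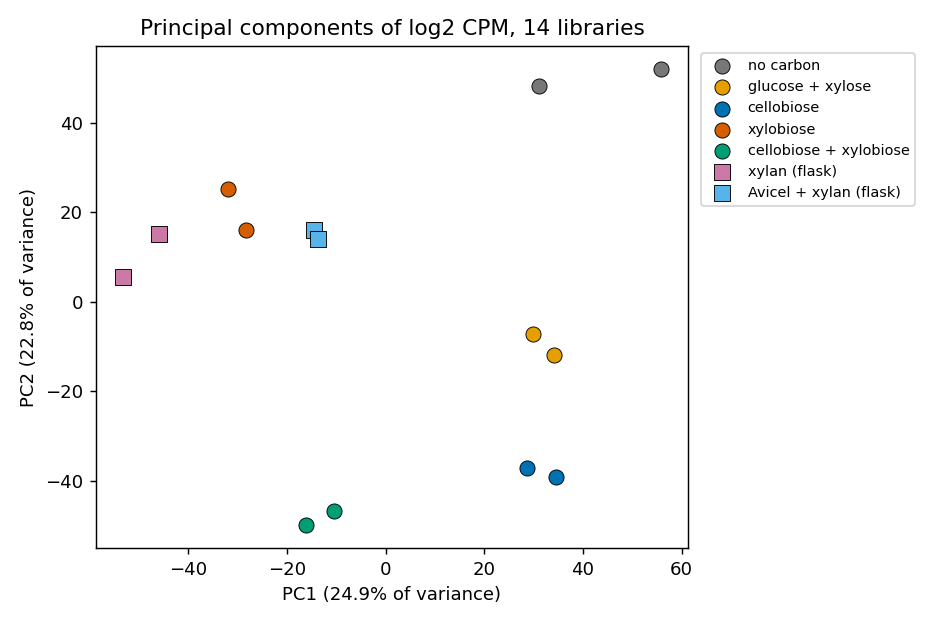
Principal components of log2 CPM for the 14 libraries, where each point is a library, squares mark flask cultures and circles plate cultures, and the axes carry 24.9% and 22.8% of the variance. The 2 libraries of each group lie nearest to each other, with NoCarbon2 at the top and G2X2 at the bottom.

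The flask cultures asked which genes respond when part of the xylan is replaced by cellulose at an equal total of 2%. Genes for cellulose breakdown, whose enzymes cut cellulose chains from the ends (cellobiohydrolases), within the chain (endoglucanases) or by oxidation, were higher with Avicel plus xylan than with xylan alone. The cellobiohydrolase gene cbh-1 (MYCTH_109566) rose from 225 ± 137 to 3645 ± 211 CPM (log2 fold change 4.02 ± 0.63, adjusted p = 0.000767). The cellobiohydrolase gene cbh-2 (MYCTH_66729) rose by 3.98 ± 0.50, the endoglucanase gene eg-1 (MYCTH_111372) by 4.66 ± 0.55 and the cellobiose dehydrogenase gene cdh (MYCTH_111388) by 4.12 ± 0.58. The cellodextrin transporter gene cdt-2 (MYCTH_114107) rose from 309 ± 162 to 2139 ± 254 CPM (2.79 ± 0.41, adjusted p = 0.000481). Of the 13 cellulase and lytic polysaccharide monooxygenase (LPMO) loci, 9 rose, 0 fell and 4 were not called (camera adjusted p = 1.77e-08; adjusted p = 0.223 with an estimated correlation).

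Regulator genes moved in the same comparison. The gene clr-2 (MYCTH_38704), which encodes a transcription factor needed for cellulase genes in related fungi, rose from 13.2 ± 9.54 to 163 ± 32.4 CPM (3.63 ± 0.54, adjusted p = 0.000575), and the xylanase regulator gene xyr-1 (MYCTH_2310145) rose by 1.99 ± 0.29. The intracellular beta-glucosidase gene gh1-1 (MYCTH_115968) rose by 2.28 ± 0.31, whereas the protease gene alp-1 (MYCTH_2303011) fell (-1.70 ± 0.32, adjusted p = 0.00216). Although the XA medium held less xylan, 2 of the 4 xylanase loci were higher in it: MYCTH_49824 at 1619 and 1361 CPM in the XA libraries against 486 and 565 in the Xylan libraries (adjusted p = 0.0254) and MYCTH_112050 by 1.40 ± 0.39 (adjusted p = 0.0166). As a list the xylanases were not called (camera adjusted p = 0.366). The largest rises without a name were MYCTH_2110715 (5.68 ± 0.64) and MYCTH_110651 (5.07 ± 0.69), and the largest falls MYCTH_78093 (-6.10 ± 0.81) and MYCTH_2072383 (-4.99 ± 0.67). In all, 2731 of 8567 genes were called, 1270 higher and 1461 lower, or 1582 higher and 1265 lower with upper-quartile scaling. The xylanase calls were lost on leaving out single libraries: for MYCTH_49824 any of the 4 (adjusted p 0.0704 to 0.117), and for MYCTH_112050 either Xylan library or XA replicate 1 (0.0688 to 0.0935). The count of genes was 1337 without Xylan replicate 2, 1271 without XA replicate 1 and 1203 without XA replicate 2.

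Cellobiose against no carbon addressed what the cellulose-derived disaccharide does on its own. It raised most cellulase genes on the list and no xylanase gene. The cellobiohydrolase gene cbh-2 went from 97.6 ± 43.5 to 1902 ± 614 CPM (4.29 ± 0.50, adjusted p = 8.72e-05), and eg-1 from 1.10 ± 0.124 to 171 ± 91.4 CPM (7.27 ± 0.62, adjusted p = 1.04e-05). The second listed endoglucanase, eg-2 (MYCTH_86753), rose by 4.51 ± 0.36, LPMO9J (MYCTH_112089) by 6.91 ± 0.72 and cdh by 4.02 ± 0.57. LPMO9B (MYCTH_80312) rose by 1.75, and its call was lost without G2 replicate 1 (1.11) or either NoCarbon2 library (1.65 and 1.86). LPMO9D (MYCTH_92668) rose by 2.15, a call lost without NoCarbon2 replicate 2 (2.06) or G2 replicate 1 (2.07). Among the 13 cellulase and LPMO loci, 11 rose and 0 fell (camera adjusted p = 1.13e-11; adjusted p = 0.194 with an estimated correlation). No xylanase locus rose, and MYCTH_89603 fell (-1.38 ± 0.44, adjusted p = 0.0343).

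Cellobiose also raised clr-2 (3.18 ± 0.53), xyr-1 (1.69 ± 0.28) and gh1-1, the last from 61.6 ± 18.1 to 413 ± 93.2 CPM (2.75 ± 0.32, adjusted p = 6.36e-05). The glucose transporter gene glt-1 (MYCTH_108924) rose from 10.3 ± 5.88 to 255 ± 100.3 CPM (4.63 ± 0.62). The arabinose transporter gene lat-1 (MYCTH_95427) fell (-1.44 ± 0.40, adjusted p = 0.0193). Among unnamed genes, MYCTH_69746 (7.83 ± 0.98) and MYCTH_108317 (7.39 ± 0.87) rose most. Of those that fell most, MYCTH_2308031 went from 195 ± 89.0 to 0.329 ± 0.0829 CPM, and MYCTH_107763 from 84.6 and 103 CPM to 2 counts in 1 G2 library and 0 in the other. In all, 2274 genes were called, 1056 higher and 1218 lower. The count was 1263 without G2 replicate 1 and 1150 without G2 replicate 2, and 1456 with only the 2 contrasted groups in the fit. The cbh-1 rise (2.44 ± 0.59) was not called without G2 replicate 1 (adjusted p = 0.0821) or NoCarbon2 replicate 2 (0.0747), the MYCTH_89603 fall without NoCarbon2 replicate 1 (0.17) or either G2 library (0.166 and 0.124), and the lat-1 fall without any of the 4 libraries (0.0544 to 0.107).

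Xylobiose against no carbon addressed what the xylan-derived disaccharide does on its own. It raised the genes for xylanases, enzymes that cut the xylan backbone. MYCTH_89603 rose from 31.3 ± 9.99 to 9181 ± 4887 CPM (adjusted p = 2.22e-06), MYCTH_49824 by 7.46 ± 0.60, MYCTH_112050 by 6.09 ± 0.48 and MYCTH_56237 by 3.25 ± 0.36, so that all 4 xylanase loci rose (camera adjusted p = 3.13e-10; adjusted p = 0.126 with an estimated correlation). The transporter gene cdt-2 rose from 103 ± 34.0 to 2338 ± 1231 CPM (4.51 ± 0.45, adjusted p = 1.94e-05), more than with cellobiose (252.6 ± 56.7 CPM). The protease gene alp-1 rose by 1.69 ± 0.32 (adjusted p = 0.00156).

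Xylobiose raised 5 of the 13 cellulase and LPMO loci and lowered 0, among them LPMO9B (MYCTH_80312; 4.12 ± 0.53), eg-1 (2.80 ± 0.57, or 1.63 without X2 replicate 2) and eg-2 (1.76 ± 0.32) (camera adjusted p = 0.00988; adjusted p = 0.556 with an estimated correlation). The other 2, LPMO9D (MYCTH_92668) and LPMO9H (MYCTH_46583), were not called without X2 replicate 2 (adjusted p = 0.129 and 0.450), without NoCarbon2 replicate 2 (0.0683 and 0.134) or with only the contrasted groups in the fit (0.0866 and 0.0703). The gene gh1-1 stayed at 63.1 ± 24.2 CPM, a difference of 0.03 on the log2 scale with a 95% interval from -0.61 to 0.68; it was -0.24 without NoCarbon2 replicate 1 and -0.43 without X2 replicate 2. Unnamed MYCTH_2066457 rose from 0.496 ± 0.18 to 1615 ± 1046 CPM (11.65 ± 0.69), while MYCTH_2307990 (-6.52 ± 0.57) and MYCTH_2297595 (-6.22 ± 0.68) fell most. In all, 3308 genes were called, 1640 higher and 1668 lower. The X2 libraries differed in level: MYCTH_89603 stood at 5725 CPM in replicate 1 and 12640 CPM in replicate 2, cdt-2 at 1467 and 3208 CPM, and the 10 most abundant genes took 8.51% and 12.4% of counts. With only the 2 contrasted groups in the fit the count was 1506.

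The 2 disaccharides were compared directly at equal mass, dose and time; cellobiose joins glucose units and xylobiose joins xylose units. All 4 xylanase loci were higher with xylobiose, from 3.29 ± 0.36 for MYCTH_56237 to 9.57 ± 0.60 for MYCTH_89603 (camera adjusted p = 4.26e-12; adjusted p = 0.093 with an estimated correlation). Among the 13 cellulase and LPMO loci, 8 were lower with xylobiose and LPMO9B alone was higher (2.37 ± 0.49, or 1.23 without X2 replicate 2) (camera adjusted p = 8.23e-05; adjusted p = 0.379 with an estimated correlation). Among the lower loci were LPMO9J (-5.90 ± 0.69), eg-1 (-4.47 ± 0.53) and cbh-2 (-3.54 ± 0.49). LPMO9E (MYCTH_79765; -1.87) and LPMO9A (MYCTH_85556; -1.52) were counted with them. The LPMO9E call was lost without G2 replicate 1 (-1.23) or X2 replicate 2 (-1.74). That of LPMO9A was lost without either G2 library (-1.31 and -1.70) or X2 replicate 1 (-1.22). The disaccharide genes split: cdt-2 was higher with xylobiose (3.21 ± 0.42, adjusted p = 0.000209) and gh1-1 lower (-2.71 ± 0.32, adjusted p = 9.16e-05). The regulator genes clr-2 (-3.17 ± 0.54) and xyr-1 (-2.25 ± 0.29) were lower with xylobiose, and alp-1 was higher (2.17 ± 0.33). Among unnamed genes, MYCTH_62925 was lower with xylobiose (-5.79 ± 0.40), and MYCTH_81364 stood at 27.8 ± 16.5 CPM with xylobiose against 2 counts in 1 G2 library and 0 in the other. In all, 3213 genes were called, 1649 higher and 1564 lower with xylobiose, or 1474 and 1762 with upper-quartile scaling. The count was 1995 without G2 replicate 1, 1525 without G2 replicate 2 and 1955 without X2 replicate 2.

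**Figure D2:**
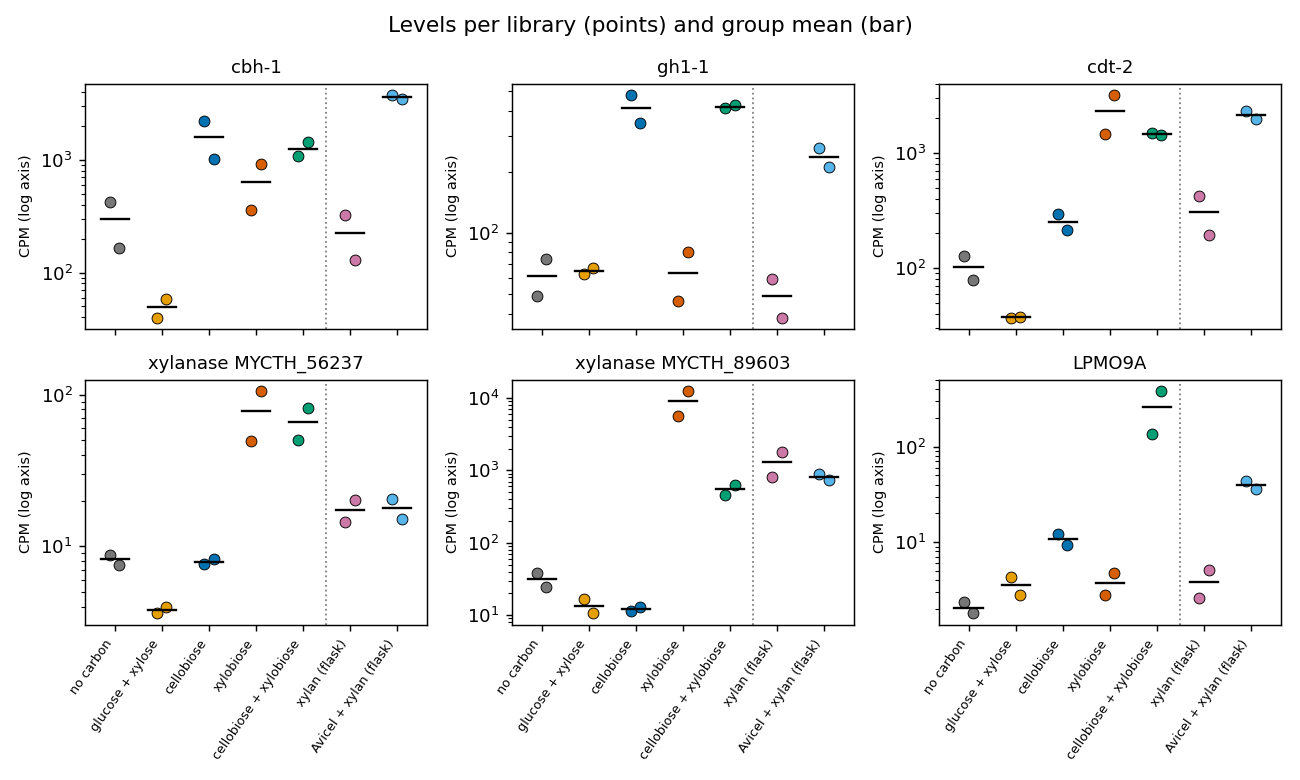
Levels of 6 listed genes in CPM on log axes, by group, where points are libraries, bars are means of 2, and the dotted line parts plate from flask cultures. The beta-glucosidase gene gh1-1 is high in G2, G2X2 and XA, the 2 xylanase genes shown lie higher in the groups given xylobiose or xylan than in the others, and LPMO9A is highest in G2X2, at 261 ± 176 CPM.

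Glucose with xylose tested the monosaccharides that make up both polymers. It did not raise the cellulase and LPMO loci as a list: 2 of 13 rose, 3 fell and 8 were not called (camera adjusted p = 0.824). The loci that rose were eg-1 (2.58 ± 0.56) and eg-2 (1.70 ± 0.32). The loci that fell were cbh-1, LPMO9H and eg-45 (MYCTH_76901), of which none was called without NoCarbon2 replicate 1 (adjusted p = 0.0694, 0.223 and 0.0604) or GX replicate 1 (0.0793, 0.15 and 0.13). LPMO9H was also not called without GX replicate 2 (0.125), nor eg-45 without GX replicate 2 (0.0829) or NoCarbon2 replicate 2 (0.0530). The cellobiohydrolase gene cbh-1 fell from 296 ± 185 to 49.4 ± 13.4 CPM (-2.59 ± 0.59, adjusted p = 0.00798), and cdt-2 fell from 103 ± 34.0 to 37.4 ± 0.305 CPM (-1.46 ± 0.40, adjusted p = 0.0187). No xylanase locus rose, and MYCTH_56237 fell (-1.11 ± 0.36, adjusted p = 0.0388), a call lost without NoCarbon2 replicate 1 (0.129), NoCarbon2 replicate 2 (0.0618), GX replicate 1 (0.183) or GX replicate 2 (0.132), and with upper-quartile scaling (0.0521), plate libraries only (0.0511) or only the contrasted groups (0.0568). The genes glt-1 (2.74 ± 0.58) and alp-1 (1.51 ± 0.32) rose, and the regulator gene clr-1 (MYCTH_2298863) fell (-1.60 ± 0.29, adjusted p = 0.00161). The fall of clr-1 was not particular to the monosaccharides. It was -0.93 in X2 and -1.34 in G2X2 versus NoCarbon2, or -0.44 and -0.84 without NoCarbon2 replicate 1. Unnamed MYCTH_112805 (7.78 ± 0.71, or 11.95 without NoCarbon2 replicate 1) and MYCTH_69746 (7.60 ± 0.97) rose most, and MYCTH_2308031 (-8.75 ± 0.51) and MYCTH_2307942 (-7.23 ± 1.00) fell most. In all, 2060 genes were called, 938 higher and 1122 lower, or 1035 and 976 with upper-quartile scaling. The count was 995 without GX replicate 1, 1058 without GX replicate 2 and 1055 with only the contrasted groups. The fall of cdt-2 was not called without NoCarbon2 replicate 1 (adjusted p = 0.12), GX replicate 1 (0.107) or GX replicate 2 (0.0991), nor the alp-1 rise with only the contrasted groups (0.0612).

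The mixture of both disaccharides raised both sets of genes. Against no carbon, 11 of the 13 cellulase and LPMO loci rose (camera adjusted p = 2.19e-10; adjusted p = 0.21 with an estimated correlation) and all 4 xylanase loci rose (camera adjusted p = 2.92e-07; adjusted p = 0.162 with an estimated correlation). The largest rise among the listed loci was that of LPMO9A (MYCTH_85556), from 2.06 ± 0.385 to 261 ± 176 CPM (6.98 ± 0.56, adjusted p = 3.28e-06). The genes cbh-2 (3.60 ± 0.49), cdt-2 (3.83 ± 0.43) and gh1-1 (2.76 ± 0.32) rose as well, and lat-1 fell (-2.03 ± 0.41). Unnamed MYCTH_2066457 (10.11 ± 0.66) and MYCTH_69746 (9.17 ± 1.03) rose most. MYCTH_2067426 had no count in either G2X2 library and was at least 296-fold lower, against a floor of 3 counts over the group, and MYCTH_2309773 fell (-10.40 ± 0.77). In all, 3276 genes were called, 1666 higher and 1610 lower, or 1540 and 1670 with DESeq2 size factors and 1453 and 1738 with upper-quartile scaling. The count was 1971 with only the contrasted groups in the fit.

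Adding xylobiose to cellobiose raised the xylanase genes without a called loss at any cellulase locus. All 4 xylanase loci rose, from 3.05 ± 0.36 for MYCTH_56237 to 6.41 ± 0.49 for MYCTH_112050 (camera adjusted p = 1.41e-15; adjusted p = 0.093 with an estimated correlation), and cdt-2 rose by 2.53 ± 0.41. The sole call among the 13 cellulase and LPMO loci was LPMO9A, which rose from 10.8 ± 2.07 to 261 ± 176 CPM (4.60 ± 0.49, adjusted p = 0.000138). Over the 13 loci the median was -0.23 and the mean 0.36 (camera adjusted p = 0.366). For cbh-2 the difference was -0.69 with a 95% interval from -1.65 to 0.27 (-0.31 without G2 replicate 1), and for gh1-1 0.02 with an interval from -0.63 to 0.66 (-0.20 without G2 replicate 2 and -0.0096 without G2X2 replicate 2). Unnamed MYCTH_100068 rose from 0.286 ± 0.213 to 370.5 ± 235 CPM (10.33 ± 0.90) and MYCTH_2066457 by 7.45 ± 0.57. MYCTH_2314555 fell from 1447 ± 548 to 17.8 ± 0.243 CPM (-6.34 ± 0.62) and MYCTH_2301682 fell as well (-6.64 ± 0.86, or -11.94 without G2X2 replicate 2). In all, 1308 genes were called, 705 higher and 603 lower, of which 53.9% were higher, or 42.2% with upper-quartile scaling. The count was 712 without G2 replicate 1, 409 without G2 replicate 2, 798 without G2X2 replicate 1 and 817 without G2X2 replicate 2.

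Adding cellobiose to xylobiose raised most of the listed cellulase genes and lowered 2 of the xylanase genes. Of the 13 cellulase and LPMO loci, 9 rose and 0 fell (camera adjusted p = 1.13e-07, or 0.223 with an estimated correlation). Among the 9 were cbh-2 at 2.86 ± 0.47, eg-1 at 3.53 ± 0.51 and LPMO9A at 6.12 ± 0.53. LPMO9D, also counted, rose from 1.82 ± 0.959 to 4.86 ± 1.11 CPM (1.43, or 0.97 without X2 replicate 1). Its call was lost with the replicate block (adjusted p = 0.0530), with plate libraries only (0.0590) or with only the contrasted groups (0.122). Of the 4 loci not called, cbh-1 stood at 639 ± 393 CPM with xylobiose and 1255 ± 249 in the mixture. LPMO9B, also not called, had a lower mean in the mixture, 56.4 ± 6.87 against 113 ± 86.6 CPM. The xylanase gene MYCTH_89603 fell from 9181 ± 4887 to 547 ± 128 CPM (-4.07 ± 0.47, adjusted p = 0.000149) and MYCTH_49824 from 1438 ± 1038 to 292 ± 61.5 CPM (-2.30 ± 0.47, adjusted p = 0.00416; -1.25 without X2 replicate 2). MYCTH_112050 did not pass the test (-0.13, 95% interval -0.95 to 0.70; 0.85 without X2 replicate 2 and 0.01 without G2X2 replicate 1). Nor did cdt-2 (-0.68, interval -1.52 to 0.17; 0.0063 without X2 replicate 2). The xylanase list was called lower (camera adjusted p = 0.0385; adjusted p = 0.507 with an estimated correlation). The genes gh1-1 (2.73 ± 0.32), clr-2 (2.52 ± 0.53) and xyr-1 (1.42 ± 0.28) rose, and alp-1 fell from 2346 ± 514 to 377 ± 116 CPM (-2.64 ± 0.33). Unnamed MYCTH_82772 (6.62 ± 0.81) and MYCTH_69746 (6.25 ± 0.90) rose most, and MYCTH_38458 (-6.68 ± 0.83) and MYCTH_2309773 (-6.07 ± 0.68) fell most. In all, 2573 genes were called, 1252 higher and 1321 lower. The count was 1445 without X2 replicate 2, 1369 without G2X2 replicate 1 and 1170 with only the contrasted groups in the fit.

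Against glucose with xylose, the disaccharide mixture raised nearly the whole set of listed hydrolase genes. Of the 13 cellulase and LPMO loci 12 rose (camera adjusted p = 3.47e-16; adjusted p = 0.14 with an estimated correlation), and so did all 4 xylanase loci (camera adjusted p = 4.26e-12; adjusted p = 0.093 with an estimated correlation). The transporter gene cdt-2 stood at 1461 ± 25.8 CPM against 37.4 ± 0.305 (5.29 ± 0.47, adjusted p = 1.88e-05), and gh1-1 at 418 ± 10.1 against 64.7 ± 3.14 CPM (2.69 ± 0.32). The protease gene alp-1 was lower in the mixture (-2.46 ± 0.33). Unnamed MYCTH_100068 (10.42 ± 0.89) and MYCTH_2066457 (7.95 ± 0.59) rose most, and MYCTH_81817 (-7.87 ± 0.70) and MYCTH_107763 (-5.36 ± 0.84, or -3.32 without GX replicate 2) fell most. In all, 2271 genes were called, 1227 higher and 1044 lower, of which 54% were higher, or 39.7% with upper-quartile scaling, which shifted the median gene by -0.14. Total sugar was 4% in the mixture and 2% in GX, so dose and kind of sugar differ together; the count was 1458 without G2X2 replicate 1, 1081 without GX replicate 1 and 1118 without GX replicate 2.

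**Figure D3:**
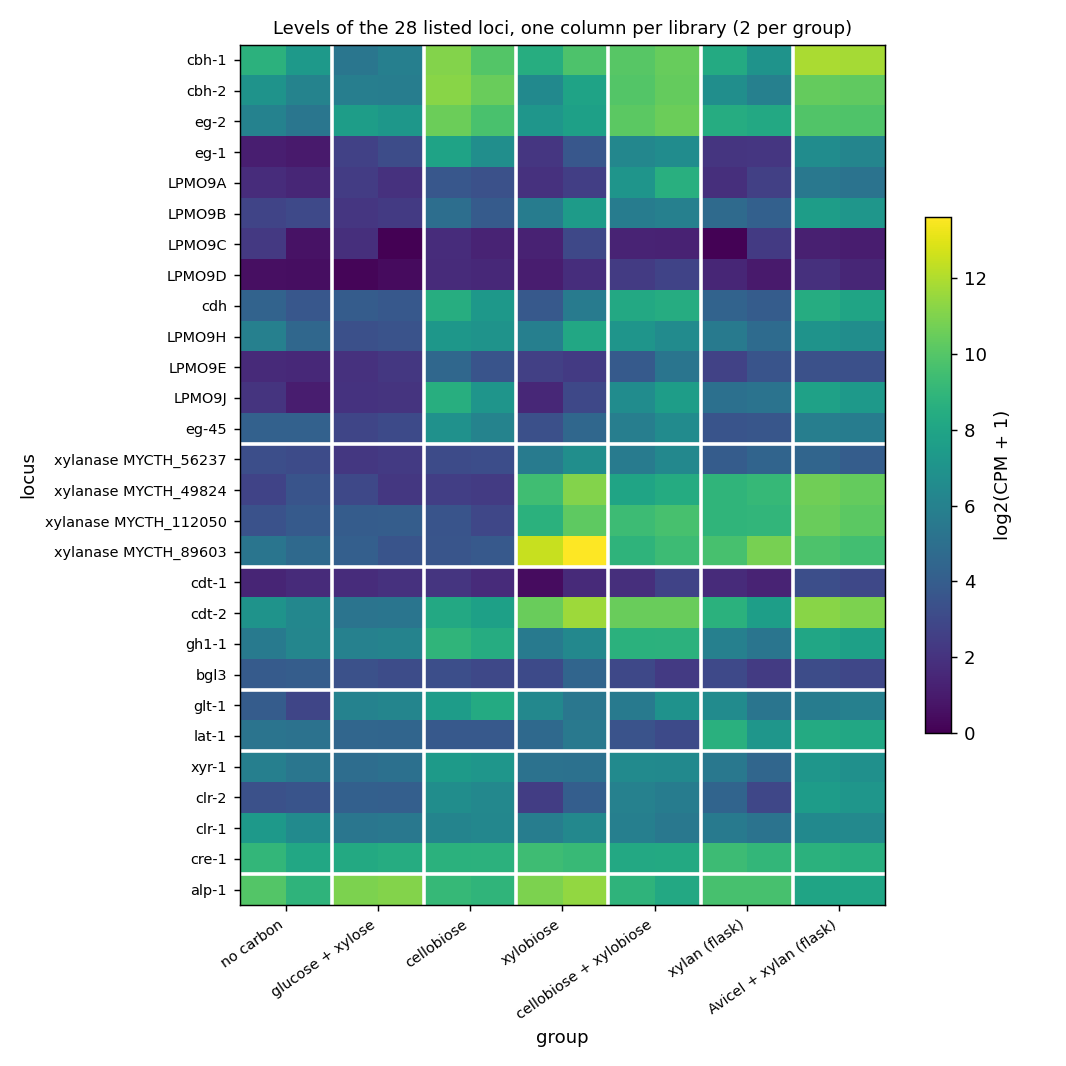
Levels of the 28 listed loci as log2(CPM + 1), with a column for each library and groups separated by white lines. Rows run from cellulase and LPMO loci through xylanases, disaccharide uptake and cleavage, monosaccharide transport and regulators to a protease, and the brightest cells are MYCTH_89603 in X2, at 5725 and 12640 CPM.

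Whether the mixture equals the sum of its parts on the log2 scale was tested as the difference between the xylobiose effect with and without cellobiose. Additivity on this scale means that fold changes multiply, so a gene below it need not be lower in the mixture than with 1 sugar. From cellobiose alone to the mixture, eg-2 went from 1194 ± 484 to 1328 ± 247 CPM, and eg-1 from 171 ± 91.4 to 88.8 ± 14.3 CPM. It departed from additivity for 1549 genes, 735 above and 814 below. Of the cellulase and LPMO loci, LPMO9A was above additivity (3.74 ± 0.68, adjusted p = 0.00372), and eg-1 (-3.74 ± 0.73), eg-2 (-1.61) and LPMO9B (-2.76, or -1.63 without X2 replicate 2) were below. Among the xylanase loci, MYCTH_89603 was below (-2.69 ± 0.61, adjusted p = 0.0105). The call for eg-2 was lost without NoCarbon2 replicate 2 (adjusted p = 0.0706), G2 replicate 1 (0.115), X2 replicate 2 (0.0878) or G2X2 replicate 1 (0.0969), with plate libraries only (0.0564) or with only the contrasted groups (0.078), and that for LPMO9B without G2 replicate 1 (0.0698) or G2X2 replicate 1 (0.0597). The count was 930 without G2 replicate 1, 778 without G2 replicate 2, 971 without G2X2 replicate 1 and 804 with only the contrasted groups in the fit.

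Genes were sorted by the disaccharide that raised them. The cellobiose-preferring class, raised by cellobiose over no carbon and over xylobiose, held 427 genes, including cbh-2, eg-1, eg-2, cdh, gh1-1, xyr-1 and clr-2. The xylobiose-preferring class held 907 genes, including the 4 xylanase loci, cdt-2, LPMO9B and alp-1, and 327 genes were raised by both with no called difference. In the mixture, 204 of the cellobiose-preferring genes (47.8%) and 460 of the xylobiose-preferring genes (50.7%) were above no carbon. Glucose with xylose raised 184 (43.1%) and 206 (22.7%) of these classes over no carbon, and lowered 5 and 93. Of the 327 genes raised by both disaccharides it raised 184 (56.3%) and lowered 1. Over all 8567 genes, 1666 were higher in the mixture than with no carbon, and glucose with xylose raised 938 and lowered 1122. These calls and the classes rest on the same NoCarbon2 libraries. A low value there can give both membership and a rise, so the shares cannot show a response to the monosaccharides. Of the cellobiose-preferring genes 160 were lower in the mixture than with cellobiose alone, and of the xylobiose-preferring genes 415 were lower than with xylobiose alone. The classes were chosen on the G2 and X2 libraries that these falls are measured from, which by itself moves chosen genes back towards the other groups. The cellobiose-preferring class held 270 genes without G2 replicate 1 and 170 without G2 replicate 2, the xylobiose-preferring class 503 without G2 replicate 2 and 536 without X2 replicate 2, and the class raised by both 209 without G2 replicate 1.

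Genes called with both disaccharides against the same no-carbon libraries were counted. There were 528 genes higher with each of them, including eg-1, eg-2 and glt-1, and 607 lower with each. Independent lists of these sizes would share 202 and 237 genes. In 20 simulations of unchanged groups against the same NoCarbon2 libraries, log2 fold changes already correlated through the shared controls. The observed correlation of the log2 fold changes across genes, 0.491, lay below the highest simulated one (mean 0.485, highest 0.520), and the share of genes with the same sign, 65.5%, lay below its simulated mean of 66.6%, while their covariance was 0.641 against 0.0716 simulated, a difference of 0.569. Noise against shared controls gives such a correlation and share of the same sign by itself, so neither value can judge the overlap. In the simulations 0 genes were called higher in both and 0 lower in both. Groups without change give few calls, so these counts cannot judge it either. Splitting the 2 control libraries would leave 1 in each part, so part of the excess over independent lists may come from the shared controls. The shared rises numbered 348 without NoCarbon2 replicate 2, 281 without G2 replicate 1 and 343 without G2 replicate 2, and the shared falls 367 and 353 without G2 replicate 1 and 2.

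A medium with cellulose-side and xylan-side carbon was set against the xylan side alone in both experiments, as XA against Xylan in flasks and as G2X2 against X2 in plates. These comparisons are unlike: XA held 1% Avicel and 1% xylan against 2% xylan, an equal total, whereas in G2X2 cellobiose came on top of 2% xylobiose and brought the total to 4%. Among the listed loci, cbh-2, eg-1, eg-2, eg-45, cdh, LPMO9A and LPMO9J rose in both, as did gh1-1, clr-2 and xyr-1, and alp-1 fell in both. The cellodextrin transporter gene cdt-1 (MYCTH_43941) was called higher in both as well, but the flask call was lost on leaving out any 1 of the 4 flask libraries (adjusted p 0.0506 to 0.125), and the plate call without X2 replicate 1 (0.162) or G2X2 replicate 2 (0.242), with plate libraries only (0.0674) or with only the contrasted groups (0.14); the plate rise was 1.84, and 3.45 without X2 replicate 2. The xylanase gene MYCTH_49824 was higher in the flask comparison (adjusted p = 0.0254, and 0.0704 to 0.117, so not called, on leaving out any 1 of the 4 flask libraries) and lower in the plate comparison (-2.30, and -1.25 without X2 replicate 2). The classes by preferred disaccharide leaned to opposite sides in the flasks. Of the 907 xylobiose-preferring genes 325 (35.8%) were lower and 82 (9.04%) higher in XA than in Xylan. Of the 427 cellobiose-preferring genes 116 (27.2%) were higher and 31 (7.26%) lower. Over all 8567 genes 1270 were higher and 1461 lower, and these shares were not tested. The overlap of XA versus Xylan with G2X2 versus X2 across all genes did not exceed that of independent lists. There were 197 genes higher in both against 186 expected (odds ratio 1.09, one-sided Fisher's exact p = 0.174), and 223 lower in both against 225 expected (odds ratio 0.986, p = 0.585). A further 221 genes were higher in the flask comparison and lower in the plate comparison, and 200 the reverse. The genes higher in both numbered 118 and 98 without Xylan replicate 1 and 2 and 80 and 79 without XA replicate 1 and 2, and those lower in both 139 without Xylan replicate 2, 92 and 89 without XA replicate 1 and 2, and 128 and 136 without G2X2 replicate 1 and 2.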

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

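The tests on LPMO9A and on MYCTH_89603 were chosen only after the results they examine had been seen, whereas those on the X2 replicates were set beforehand. For the stronger response of X2 replicate 2, however, the need to exceed the other groups was added after its result was seen, and under the bound first set that explanation would have been met. The xylobiose effect differed with and without cellobiose, by a test of that difference, for 1549 genes. Among the listed loci called, the difference on the log2 scale was 3.74 for LPMO9A (MYCTH_85556) and negative for the others: -1.61 for eg-2 (MYCTH_86753), -3.74 for eg-1 (MYCTH_111372), -2.76 for LPMO9B (MYCTH_80312), -2.69 for the xylanase MYCTH_89603, -1.98 for cdt-2 (MYCTH_114107), -4.18 for glt-1 (MYCTH_108924), -1.09 for cre-1 (MYCTH_2310085) and -2.16 for alp-1 (MYCTH_2303011). The calls for eg-2, LPMO9B, cdt-2 and cre-1 were lost on leaving out single libraries: G2 replicate 1 (adjusted p = 0.115, 0.0698, 0.096 and 0.0877) or G2X2 replicate 1 (0.0969, 0.0597, 0.0818 and 0.111) ended all 4. Those of eg-2, cdt-2 and cre-1 also ended without NoCarbon2 replicate 2 (0.0706, 0.0834 and 0.0814) or X2 replicate 2 (0.0878, 0.113 and 0.0559; without that library the difference was -1.63 for LPMO9B and -1.30 for cdt-2), those of cdt-2 and cre-1 without G2X2 replicate 2 (0.072 and 0.0766), and that of cre-1 without G2 replicate 2 (0.118) or X2 replicate 1 (0.0885). The calls of eg-2 and cre-1 were also lost with plate libraries only (0.0564 and 0.084) and with only the contrasted groups in the fit (0.078 and 0.127).

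Among unnamed genes the difference was 6.70 for MYCTH_107763, 6.35 for MYCTH_2307943, -9.22 for MYCTH_2301682 and -10.09 for MYCTH_2314555. MYCTH_107763 had 2 counts in 1 G2 library and 0 in the other, so its value depends on the prior count; it was not called without G2 replicate 1 (adjusted p = 0.0681), G2 replicate 2 (0.0527) or G2X2 replicate 1 (0.0641). MYCTH_2301682 had 0 and 9 counts in the G2X2 libraries, and its difference was -14.52 without G2X2 replicate 2. MYCTH_2314555 rose with cellobiose (5.35 ± 0.59) and with xylobiose (3.75 ± 0.54), and stood at 17.8 ± 0.243 CPM in the mixture against 35.4 ± 9.09 CPM with no carbon.

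LPMO9A stood at 10.8 ± 2.07 CPM with cellobiose, 3.78 ± 1.34 with xylobiose and 261 ± 176 with both. A single library does not account for it, since the lowest departure from additivity over 8 refits without 1 library was 2.80 and each refit called it (highest adjusted p 0.0198). Reads shared with the 6 other listed LPMO loci do not account for it either, as the largest rise among them from G2 to G2X2 was 1.36 against 4.60 for LPMO9A; LPMO genes outside the list were not examined. The higher total sugar in the mixture (4% against 2%) cannot be told apart from the presence of both sugars: in flasks at an equal total the gene rose by 3.36, but cellobiose alone also raised it (2.38 ± 0.49). A joint response to both disaccharides is a candidate explanation that stays open.

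The X2 replicates differed in level for some xylobiose-raised genes, such as 12640 CPM in replicate 2 against 5725 in replicate 1 for MYCTH_89603. Genes raised (705) or lowered (603) by xylobiose in other libraries, G2X2 against G2, were examined for the same difference. The median difference, replicate 2 over replicate 1 on the log2 scale, was only 0.081 for the raised genes and -0.198 for the lowered ones. These medians stood apart by 0.279, with a bootstrap SE of 0.0423 that resamples genes and not libraries. A scaling error alone would move all genes alike and leave no such gap. Gaps at least as large occurred between replicates of other groups, so the gap cannot decide on a scaling error. The correlation of the difference with gene length was only 0.033 across genes, which argues against a steady trend with length. Other effects of gene length stay open, since the smallest such difference over 5 length classes was 0.12 with SEs up to 0.102. A stronger response of that culture stays open too: 60.2% of these genes differed in its direction, and the bound set beforehand, a value above 0, was too weak, since the difference of medians was 0.45 between the Xylan replicates and -0.37 between the G2 replicates.

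The xylanase gene MYCTH_89603 fell from X2 to G2X2 by 4.07 on the log2 scale while cdt-2 was not called (-0.68, and 0.0063 without X2 replicate 2). Library scaling does not account for it, since the ratio of MYCTH_89603 to cdt-2 within each library was 1.96 and 1.98 (log2) in X2 but -1.70 and -1.18 in G2X2, a difference of -3.41 between means. The high X2 replicate 2 alone does not account for it either, as without that library the fold change was -3.38 (adjusted p = 0.000912). Whether a cellulose-side sugar lowers the gene in flasks too stays open, at -0.67 for XA against Xylan (adjusted p = 0.235), or -1.11 without Xylan replicate 1 and -0.01 without Xylan replicate 2. A lowering by cellobiose, or by the higher total sugar, may explain the plate result, and the design does not part them.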

How the results depend on the processing

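With 2 libraries per group, counts of calls depend on thresholds and on single libraries. A lone library left in a group is assumed to vary like the other groups. DESeq2 size factors and the DESeq2 Wald test kept the counts of the 10 comparisons, the classes and the overlaps within 1.5 times, and upper-quartile factors and no filter, run for the 10 comparisons alone, kept those. Which direction held more calls turned over under at least 1 alternative in each comparison except G2 versus NoCarbon2. Replicate numbers only number the samples: same-numbered libraries' deviations correlated at -0.16 to 0.21, and with a replicate block the counts were 2562 for XA versus Xylan, 2075 for G2, 3153 for X2, 3110 for G2X2 and 1876 for GX versus NoCarbon2. Of 2600 alternative values for 196 called pairs of a named gene and a comparison, 2434 kept direction and call, 166 lost the call and 0 changed sign; of the lost calls, 109 came with 1 library left out, 35 at adjusted p under 0.01, 17 with fewer groups in the fit, 3 at a fold of at least 2, 1 under upper-quartile scaling and 1 with the replicate block.

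At a fold of at least 2, fewer genes pass by construction: 1522 for XA versus Xylan, 1436 for G2, 1976 for X2, 1990 for G2X2 and 1254 for GX versus NoCarbon2, 1812 for X2 versus G2, and 844, 1400 and 1344 for G2X2 versus G2, X2 and GX. The classes then held 235, 504 and 167 genes (cellobiose-preferring, xylobiose-preferring, both), 242 genes were higher with both disaccharides, and flask and plate shared 66 higher and 113 lower. At adjusted p under 0.01 the counts in the same order were 1380, 1232, 1964, 1992, 1094, 1764, 603, 1163 and 1141, with 582 for the departure from additivity. The classes then held 194, 486 and 157, both disaccharides shared 222 higher and 326 lower, and flask and plate 58 and 62.

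With only the contrasted groups in the fit, the counts were lower at 1456 for G2, 1506 for X2, 1971 for G2X2 and 1055 for GX versus NoCarbon2, 2222 for X2 versus G2, 1170 for G2X2 versus X2 and 804 for the departure, and higher at 3481 for XA versus Xylan, 1757 for G2X2 versus G2 and 2748 for G2X2 versus GX; the cause was not tested. Camera with an estimated correlation called 0 of the 60 list tests (32 with the preset correlation). Leaving out each library gave 1203 to 2193 for XA versus Xylan, 1150 to 2123 for G2, 2367 to 3409 for X2, 2299 to 3229 for G2X2 and 995 to 1960 for GX versus NoCarbon2, 1525 to 3293 for X2 versus G2, 409 to 817, 1369 to 2790 and 1081 to 1575 for G2X2 versus G2, X2 and GX, and 778 to 1986 for the departure. The classes ranged from 170 to 470, 503 to 1018 and 209 to 369, genes shared by both disaccharides from 281 to 617 (higher) and 353 to 621 (lower), and those shared by flask and plate from 79 to 195 and 89 to 217.

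Of 1649 alternative values for the 121 pairs not called, 48 passed the test and 91, from 59 pairs, changed sign; the cause was not tested. Values are given for the uncalled pairs that the results name, a restriction chosen after these sign changes were seen. For gh1-1 (MYCTH_115968) in X2 versus NoCarbon2 they were -0.025 with upper-quartile factors, -0.027 with the same experiment only and -0.43 to 0.37 leaving out a library. For gh1-1 in G2X2 versus G2 they were -0.011 with DESeq2 size factors, -0.079 with upper-quartile factors, -0.010 with the Wald test, -0.010 with the same experiment only, -0.011 with the contrasted groups only and -0.20 to 0.26 leaving out a library. In G2X2 versus X2, leaving out a library gave -0.69 to 0.85 for MYCTH_112050 and -1.12 to 0.0063 for cdt-2 (MYCTH_114107).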

Other observations

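The test of neighbouring genes and that of the genes highest in the disaccharide mixture were set before their results were seen; the run of 6 genes described here was singled out after its values were seen. In the chromosome order of the tested genes, genes of the sugar preference classes lay next to each other more often than random genes. Genes not tested were left out of this order, so some pairs may have such a gene between them. Among 426 cellobiose-preferring genes with a position, 42 adjacent pairs occurred against a mean of 21.2 in 10000 random draws (highest 41), and among 904 xylobiose-preferring genes 156 pairs against 95.3 (highest 131), each with a permutation p of 1e-04, the smallest these draws can give. The hypothesis that neighbouring genes share a class was met, with 198 pairs together. Pairs across classes were not counted, so a shared preference is not told apart from neighbours that change together. Reads counted across the border of overlapping neighbours could add to such pairs and were not examined.

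The longest run in the order of tested genes held 6 cellobiose-preferring genes, from MYCTH_2064854 through MYCTH_82782, MYCTH_11658, MYCTH_108317 and MYCTH_69746 to MYCTH_82772. Their log2 fold changes with cellobiose over no carbon were 3.65, 5.18, 6.99, 7.39, 7.83 and 7.19 in that order, and MYCTH_82782 reached a mean of 4831 CPM with cellobiose. Glucose with xylose raised MYCTH_108317 (7.29 ± 0.87), MYCTH_69746 (7.60 ± 0.97) and MYCTH_82772 (6.68 ± 0.82) as well. None of the 6 was called in XA versus Xylan (adjusted p 0.135 to 0.946 by edgeR).

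A hypothesis was that genes higher in the disaccharide mixture than with either disaccharide or none are also higher with the mixed polymer. There were 132 genes higher in G2X2 than in each of G2, X2 and NoCarbon2, with LPMO9A the sole listed locus among them, and 47 of these were above additivity. The 132 genes were called higher in XA than in Xylan in 20 cases against 19.6 expected (odds ratio 1.03, one-sided Fisher's exact p = 0.495), so the hypothesis gained no backing. Of the 132 genes, 43 were lower in XA than in Xylan, against 22.5 expected by chance, a count that was not tested.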
